A study of Homo sapiens with 6 samples.

How the data were processed

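RNA was measured in 6 cultures of naive CD4+ T cells isolated from the blood of 3 healthy donors. Each donor gave a culture that received vehicle and a culture that received iPIP5K1a (ISA-2011B), an inhibitor of the lipid kinase PIP5K1A, on day 3 of stimulation with plate-bound anti-CD3, IL-23 and IL-1b. RNA was extracted on day 5, and each culture gave 1 library. The submitters' processing notes name RSEM 1.3.2, FastQC, DESeq2 and the genome build hg19, without saying what each was used for. The kind of library (selection of polyadenylated RNA, strand) is not given in the sources used here.

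The deposited values are treated as a score with no fixed range: the authors' table is named as TPM (the length-corrected abundance that RSEM reports) per gene, but it holds whole numbers in 100% of the entries, so the TPM were rounded or truncated before deposit. They are not read counts. The design had assumed TPM with decimals, and the test planned for TPM was kept. Among genes with 4 to 16 TPM in a donor, the variance between that donor's 2 libraries was 0.209 to 0.241 times the mean. Whole numbers that were read counts themselves would have a variance of at least about the mean. The columns sum to 740097 to 822920, so the rows of the table carry 74.0% to 82.3% of the TPM of a full table. TPM keep no sequencing depth, so the depth of each library is unknown and no counting interval or floor can be given. A step of 1 TPM is large for a low gene. A gene at 1 TPM can differ by 1.5-fold on the log2(TPM + 1) scale through a single step.

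The table has 58825 Ensembl gene identifiers. Of these, 58472 were named from a table of current symbols and 58552 are in GENCODE 29, which was used for gene types and for the names of unnamed loci. Because the notes name another build, no coordinates are given. XIST, TSIX and Y-linked genes were left out before any test (512 rows). The 14136 genes with a mean of at least 1 TPM over the 6 libraries were tested. Of all rows, 40903 were 0 in every library.

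Values were taken as log2(TPM + 1), and a fold change is on that scale, which understates the change of low genes. The main test was limma (3.58.1, R 4.3.3) with a variance trend, 2-sided, comparing 3 vehicle with 3 inhibitor libraries, with Benjamini-Hochberg adjustment over the genes tested and a threshold of 0.05. It carries no donor term. The second fit has the replicate number, hence the donor, as a block. The field for the individual gives 3 donors and puts same-numbered libraries in the same donor, whereas the sample titles carry 1 donor name for all 6 libraries. The field was used. The column names of the deposited values likewise give each replicate number its own donor, so that n = 3 donors rests on both. The deviations of same-numbered libraries from the group means correlated across genes with r = 0.56, 0.79 and 0.80, against -0.16 to -0.69 for libraries of different donors. The numbers therefore pair the libraries, and the blocked value is given wherever it changes a call or a count. Each donor is 1 biological replicate, and 3 pairs limit the precision of every comparison.

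A set of 40 lists of genes were fixed before the data were examined (T helper programmes, signalling targets, metabolism, stress, cell cycle, and markers of other cell types). The 39 lists with at least 3 tested genes were tested with limma's camera at its preset correlation of 0.01 between genes, 2-sided, adjusted over the lists. Camera with a correlation estimated from the data, and fry, a test of whether a list's genes move on balance one way, were the alternatives. Counts "adjusted over the list alone" repeat the gene test's adjustment within a list.

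The genes named were chosen by a rule written before the data were examined. It takes PIP5K1A and the members of both Th17 lists with a mean of at least 1 TPM. It takes up to 12 genes in each direction with the largest fold change among those that pass and that move the same way in every donor, filled from the fit with the donor block. A direction left with fewer than 5 is filled to 5 with the largest changes of one sign in every donor, which are said not to pass. Of each list described it takes up to 4 members with the largest absolute change. Genes outside the rule are said to be chosen after their values were seen.

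The scripts were tested on simulated tables of whole-number TPM drawn for the 14136 genes from each donor's means and the spread within pairs. Of genes changed 4-fold, 36.1% were recovered without and 61.5% with the donor block. Recovery was 4.18% and 23.9% at 2-fold, and 0% and 11.3% at 1.5-fold. Unchanged genes called per simulated table averaged 1.4 without and 5.2 with the block. A list of 20 genes shifted by 0.3 log2 units was found in 20 of 20 tables in both fits with the preset correlation, where 1 of 780 unchanged lists was called in each. The lists held random genes, and the noise within pairs was drawn independently for each gene. The rate of false calls for lists whose genes vary together was therefore not measured. With an estimated correlation it was found in 15 of 20 tables without the block and in 0 of 20 with it, so that this last combination cannot detect such a shift.

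The alternatives were a pseudocount of 0.1 or 0.5, no filter on low values, a mean of at least 5 TPM, median-of-ratios scaling, quantile normalization, no variance trend, sample quality weights, the donor block alone and with 4 of these choices, and leaving out each library and each donor. A mean of at least 10 TPM, with and without the block, and the block with an estimated correlation or with fry were added after seeing the data. Figures were drawn with matplotlib 3.10.9.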

Results

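Transcript levels were compared between vehicle and the PIP5K1A inhibitor iPIP5K1a (ISA-2011B) in human CD4+ T cells stimulated through CD3 in the presence of IL-1b and IL-23, conditions that favour Th17 genes. The comparison asks what inhibition of PIP5K1A, a kinase that makes the membrane lipid phosphatidylinositol 4,5-bisphosphate, does to Th17 gene expression. It rests on 3 vehicle and 3 inhibitor libraries, 1 of each from donors 1, 2 and 3, after 5 days of culture with the inhibitor present from day 3. Values are whole-number TPM. Between 14865 and 15787 genes were listed at 1 TPM or more in a library, and mitochondrially encoded genes took 8.24% to 9.84% of the TPM. The sequencing depth is unknown.

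The Th17 cytokine genes did not move together with the inhibitor. IL17F, the most abundant of them, was at 119 ± 94.4 TPM (SD, n = 3) with vehicle and 115 ± 108 TPM with the inhibitor, and it was lower in donor 1 but higher in donors 2 and 3. IL17A was at 3.67 ± 3.06 and 4.33 ± 3.06 TPM, equal in donors 1 and 2 and higher in donor 3. IL26 was at 33.3 ± 13.3 and 28.0 ± 7.21 TPM, IL22 at 2.67 ± 1.15 and 2.33 ± 1.15 TPM, and CSF2, which encodes GM-CSF, at 22.3 ± 5.13 and 19.3 ± 2.31 TPM. IL21 was at 4.33 ± 5.77 and 6.33 ± 7.51 TPM, and CCL20, which encodes the chemokine ligand of CCR6, at 1.67 ± 1.15 and 3 ± 1.73 TPM. Both were higher in all 3 donors. None of the 7 genes passed limma's test. With the donor as a block CCL20 passed (1.5-fold, adjusted p = 0.041), from 3, 1 and 1 TPM to 5, 2 and 2 TPM. Adjusted over the list alone, CCL20 and IL21 passed with the block and 0 genes without it. IL21 went from 1, 1 and 11 TPM to 2, 2 and 15 TPM, a single step of 1 TPM in donors 1 and 2. The list as a whole had a median log2 fold change of 0.04 (adjusted p = 0.89, camera; 0.11 with the block), and its medians per donor were -0.21, 0.42 and 0.30. Leaving out libraries moved the list's median from -0.31 (without the vehicle library of donor 2) to 0.75 (without the inhibitor library of donor 2), and without both libraries of donor 1 it was 0.29 and passed with the block (adjusted p = 0.037, and 0.22 without the block). Among its genes of at least 10 TPM, an alternative chosen after the values were seen, the median was -0.18 (adjusted p = 0.27).

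**Figure D1:**
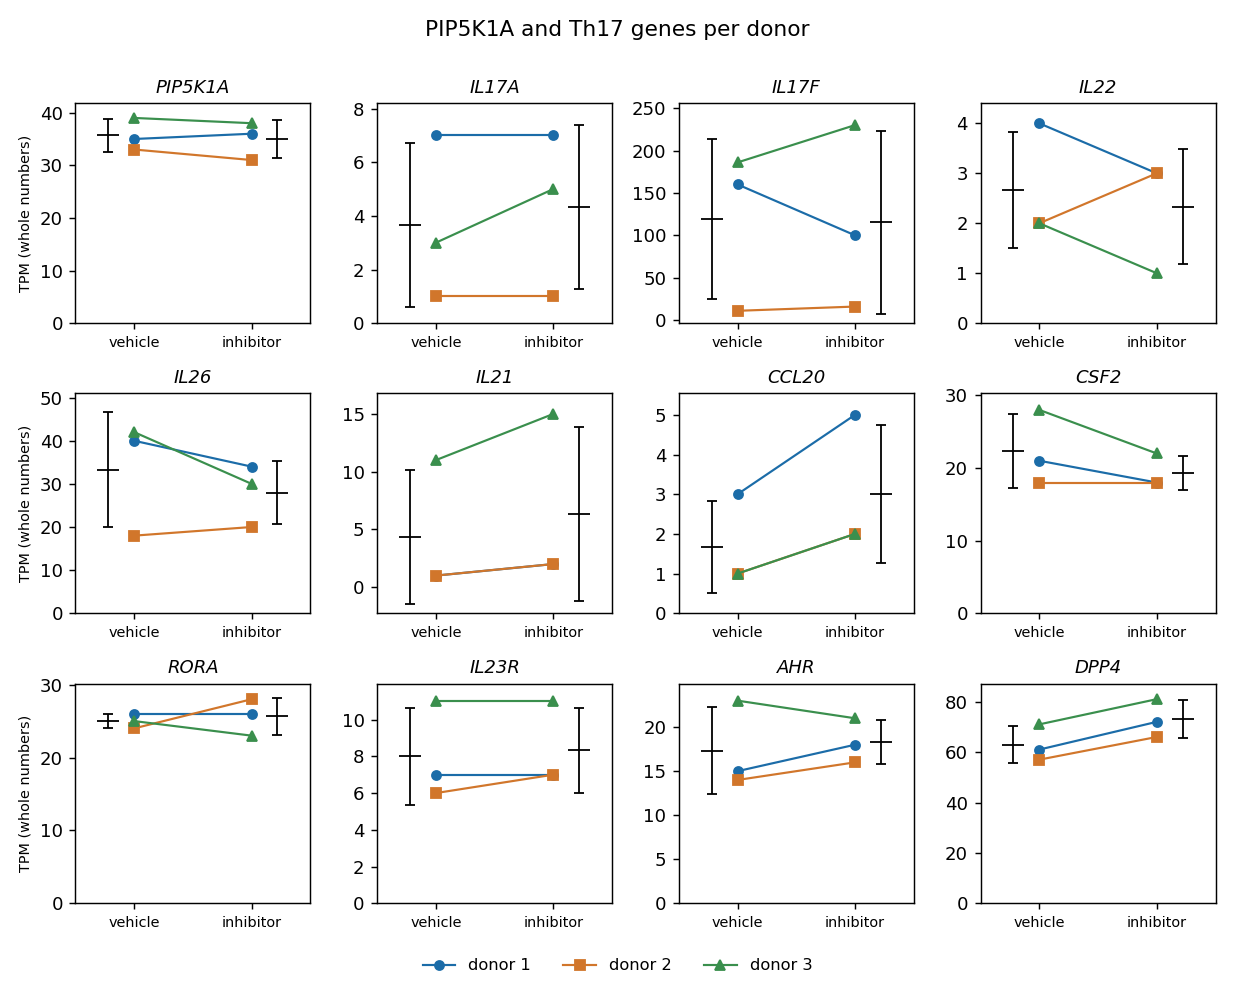
Whole-number TPM of PIP5K1A and 11 Th17 genes with vehicle and with the inhibitor, on linear axes with their own scale. Coloured points joined by a line are the 2 libraries of 1 donor, and black bars are the mean ± SD over 3 donors. Lines of different donors lie further apart than the ends of most lines, and IL17F runs down in donor 1 and up in donors 2 and 3.

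The transcription factors and receptors of the Th17 programme showed no change that passed over all genes in either fit. IL23R, a chain of the IL-23 receptor, was at 8 ± 2.65 TPM with vehicle and 8.33 ± 2.31 TPM with the inhibitor (n = 3 each). With the donor block, the 95% interval of its fold change ran from 0.909 to 1.2. The corresponding intervals were 0.832 to 1.26 for RORA, 0.794 to 1.40 for STAT3, 0.944 to 1.14 for BATF, 0.839 to 1.37 for AHR and 0.968 to 1.26 for IRF4. For the cytokine genes they were wide, from 0.478 to 2.23 for IL17F and from 0.757 to 1.73 for IL17A. DPP4, the surface peptidase CD26, was at 63.0 ± 7.21 and 73.0 ± 7.55 TPM and was higher in every donor. It did not pass over all genes (adjusted p = 1 without and 0.38 with the block), and was the 1 of 19 tested members that passed adjusted over the list alone, with the block. IL6ST, the gp130 receptor chain, was higher in every donor (1.13-fold) and CTSH, cathepsin H, lower in every donor (0.900-fold), without passing (adjusted p of 0.44 and 0.49 with the block). The remaining members lay between 0.822-fold (IL4I1) and 1.14-fold (PTPN13). They include CXCR6 (0.958), MAF (0.909), IL12RB1 (1.12), IL6R (0.944), ABCB1 (1.13) and KLRB1 (1.09), and IL1R1 was equal in both groups. CCR6, the receptor of CCL20, had a mean of 0.667 TPM and was not tested. As a list these genes had a median log2 fold change of 0.08 (adjusted p = 0.17). The shift passed with the block (adjusted p = 0.038) and not with an estimated correlation (adjusted p = 0.95 without and 0.46 with the block). The list's medians per donor were 0, 0.12 and 0, and of the 19 genes 4 were higher and 1 was lower in all 3 donors. PIP5K1A itself, the target of the inhibitor, was at 35.7 ± 3.06 TPM with vehicle and 35.0 ± 3.61 TPM with the inhibitor (0.981-fold, 95% interval 0.90 to 1.1 with the block). The 30 tested genes of phosphoinositide metabolism and signalling had a median of -0.01 (adjusted p = 0.59). Of these, the inositol phosphatase INPPL1 (0.886-fold), the calcium channel ITPR2 (0.902-fold) and SYNJ1 (0.915-fold) were among the 4 with the largest change, with OCRL at 1.14-fold, and none passed in either fit.

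Over all genes, no gene passed the threshold without the donor block, and a few low genes passed with it. Of 14136 genes, 0 were higher and 0 lower by limma's test, and 79 had an unadjusted p under 0.05 where 707 would be expected by chance without a donor effect. In simulated tables this fit recovered 4.18% of genes changed 2-fold, so its 0 calls do not show an absence of change. With the donor block 6 genes passed as higher and 0 as lower, and 1214 had an unadjusted p under 0.05, 481 higher and 733 lower. That balance depended on the scaling. With the block, 509 of 989 such genes were higher after median-of-ratios scaling and 521 of 1139 after quantile normalization. The 6 genes were CCL20, TUBB4A (a beta-tubulin), RBM8B, FGF7P3, LINC00265 and a locus of miscellaneous RNA, ENSG00000277948. TUBB4A, RBM8B, FGF7P3 and LINC00265 were listed at exactly 1 TPM in the 3 vehicle libraries and 2 TPM in the 3 inhibitor libraries (1.5-fold, adjusted p = 0.024 with the block). ENSG00000277948 went from 0, 1 and 0 to 1, 3 and 1 TPM (adjusted p = 0.011 with the block). RBM8B and FGF7P3 are copies of other genes, and reads may be split between copies. None of the 6 passed with the block after median-of-ratios scaling or quantile normalization, and no gene passed with the block among the 7829 genes of at least 10 TPM. The largest reductions of one sign in every donor did not pass. They were the pseudogenes AL158066.2 (9.67 ± 6.03 to 1.67 ± 1.53 TPM), SEPTIN14P2 (8 ± 4.36 to 2.33 ± 4.04 TPM) and PSMC1P5 (30.7 ± 15.7 to 13.7 ± 14.6 TPM), the miscellaneous RNA ENSG00000274430 (48.7 ± 33.5 to 12.7 ± 9.29 TPM) and the antisense gene DDIT4-AS1 (4.67 ± 1.53 to 1 ± 1.73 TPM). Their adjusted p was 1 without the block and between 0.38 and 0.63 with it.

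Differences between treatments were small beside those between donors. Among the 7829 genes of at least 10 TPM, the median absolute log2 fold change was 0.06, and 24 genes differed by 1.5-fold or more in either direction. The SD of the donors' mean levels had a median of 0.27 log2 units. With the block, the 95% interval of the fold change lay within 2-fold either way for 98.7% of these genes and within 1.5-fold for 92.3%. The changes of single genes were shared between donors to differing degrees: across these genes, which are not independent replicates, the log2 fold changes of pairs of donors had Pearson r of 0.09 (donors 1 and 2), 0.05 (donors 1 and 3) and 0.08 (donors 2 and 3), and Spearman's rho of 0.28, 0.10 and 0.00. Among the 2056 genes of at least 50 TPM, Pearson r was 0.30, 0.20 and 0.03. In all 3 donors 709 genes were higher and 1006 lower, which is 21.9% of the genes where 25% would arise by chance if no value were tied.

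Of the 39 lists tested, 2 were higher and 1 was lower with the inhibitor by camera. The interferon-stimulated genes, which respond to type I interferon, had the lowest adjusted p without the block. All 22 were higher on average, with a median log2 fold change of 0.28 (adjusted p = 0.0002, and 0.00028 with the block, equal to that of Th1 genes). The correlation estimated between these genes was 0.71, and 0.81 with the block, far above the preset 0.01. The 22 genes are therefore not independent observations. The call was lost with an estimated correlation (adjusted p = 0.99, and 0.62 with the block). Among them, the antiviral genes OAS1 (18.0 ± 4.58 to 28.7 ± 8.62 TPM), MX1 (19.7 ± 4.62 to 33.3 ± 17.0 TPM), IFI44L (16 ± 10.4 to 30 ± 27.6 TPM) and IFI6 (34.0 ± 3.61 to 50.3 ± 12.6 TPM) had the largest values, and none passed singly in either fit. The donors differed: the list's median was 0.61 in donor 1, -0.10 in donor 2 and 0.32 in donor 3, and 5 of the 22 genes were higher in all 3. The call was also lost without the vehicle library of donor 2 (median 0.02, adjusted p = 0.23), the inhibitor library of donor 1 (-0.05, adjusted p = 0.60) or of donor 3 (0.15, adjusted p = 0.079), and without both libraries of donor 1 (0.13, adjusted p = 0.34, or 0.037 with the block).

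Th1 genes were higher by a median log2 fold change of 0.17 (adjusted p = 0.012, and 0.00028 with the block), with 12 of 13 genes higher on average and medians per donor of 0.18, 0.17 and 0.12. The list's call was lost with an estimated correlation (adjusted p = 0.64, and 0.46 with the block). That correlation was -0.03 in both fits, below the preset 0.01. Unlike for the interferon-stimulated genes, the loss therefore does not come from a correlation above the preset. IL12RB2, a chain of the IL-12 receptor, was at 54.0 ± 37.5 TPM with vehicle and 73.0 ± 47.9 TPM with the inhibitor and was higher by 0.50, 0.45 and 0.40 log2 units in the donors. IL18R1 and IL18RAP (1.21-fold each) were further members with large values, and EOMES was at 0.801-fold. IL12RB2 passed adjusted over the list alone with the block and not without it, and did not pass over all genes in either fit. Without the block the list's call was also lost on leaving out the vehicle library of donor 1 (median 0.14, adjusted p = 0.068) or donor 2 (0.06, 0.14), the inhibitor library of donor 3 (0.08, 0.15), or both libraries of donor 1 (0.17, 0.081) or donor 2 (0.17, 0.21), and with no filter on low values (0.074) or sample quality weights (0.064). Its median was 0.10 without the inhibitor library of donor 1 and 0.11 without both libraries of donor 3, where the call was kept. Of 9 cytotoxic genes, whose products kill target cells, 5 were higher in all 3 donors, and the list passed only with the block (median 0.18, adjusted p = 0.17 without and 0.0025 with the block, 0.46 with the block and an estimated correlation). GZMB, granzyme B, was at 1792 ± 385 and 2367 ± 619 TPM, GZMH at 16.3 ± 14.4 and 23.0 ± 19.1 TPM and NKG7 at 132 ± 60.5 and 159 ± 74.3 TPM. These 3 passed adjusted over the list alone with the block, and PRF1, perforin, did not (1.15-fold). Beside these lists, the markers CD8A and CD8B stood at 1.08-fold and 1.11-fold, and the 7 NK cell markers tested had a median of 0 (adjusted p = 0.60).

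**Figure D2:**
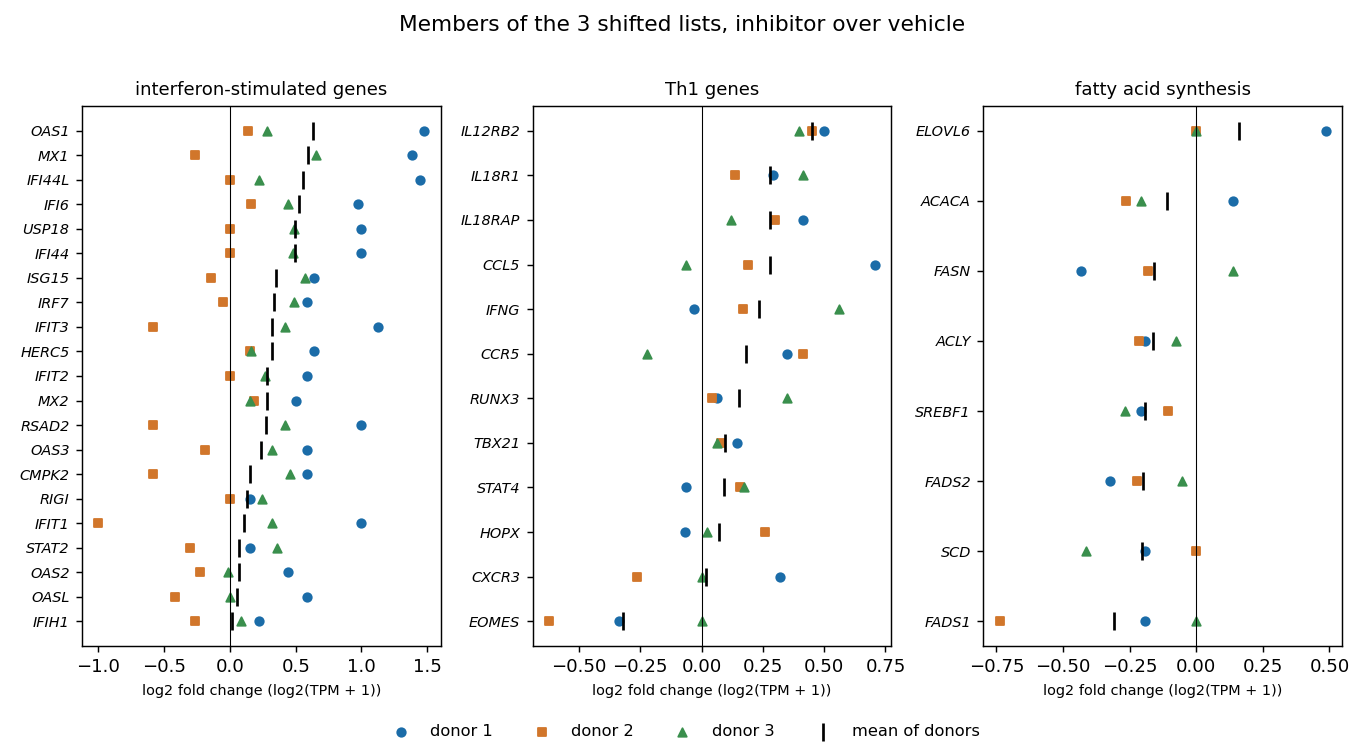
Log2 fold change, inhibitor over vehicle, of tested members of the 3 lists that passed without the donor block. Points are donors and the black bar is the mean of the 3 donors. In the interferon-stimulated genes donor 1 lies to the right and donor 2 near or below 0 (medians 0.61 and -0.10), while the Th1 medians of the donors lie between 0.12 and 0.18.

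The lists of lipid synthesis genes had medians below 0, without a member that passed singly. The 8 fatty acid synthesis genes had a median log2 fold change of -0.18 (adjusted p = 0.025, and 0.031 with the block), and 7 were lower on average. The call was lost with an estimated correlation (adjusted p = 0.64, and 0.46 with the block). That correlation was -0.07, and -0.12 with the block, below the preset 0.01, so the loss does not come from a correlation above the preset. FADS1 was at 7.67 ± 1.15 and 6 ± 1 TPM, SCD, the stearoyl-CoA desaturase, at 81.0 ± 5.29 and 70.3 ± 6.11 TPM, FADS2 at 31.7 ± 4.04 and 27.3 ± 1.53 TPM, and SREBF1, a transcription factor of lipid synthesis, at 76.3 ± 17.2 and 66.7 ± 15.2 TPM. Without the block the call was lost with quantile normalization (0.085), sample quality weights (0.13) and no filter on low values (0.087), and with the block it was kept with quantile normalization (0.023) and no filter (0.025). Without the block it was also lost on leaving out the vehicle library of donor 1 (median -0.12, adjusted p = 0.098) or donor 3 (-0.09, 0.14), the inhibitor library of donor 2 (-0.08, 0.25) or donor 3 (-0.26, 0.053), or both libraries of donor 1 (-0.17, 0.081), donor 2 (-0.14, 0.13) or donor 3 (-0.18, 0.11). Without both libraries of donor 2 or donor 3 it was lost with the block too (0.10 and 0.081). The 23 cholesterol synthesis genes had a median of -0.11, with 18 lower on average and 8 lower in all 3 donors. That list passed only with the block (adjusted p = 0.084 without and 0.0016 with the block; with an estimated correlation 0.99 and 0.46). Its largest changes were in STARD4 (0.801-fold), HSD17B7 (0.836-fold), MVK (0.848-fold) and HMGCS1, the HMG-CoA synthase (0.854-fold), none of which passed.

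In all, 16 lists passed with the donor block, 12 higher and 4 lower, and 13 of them passed only there. None passed with an estimated correlation, where the adjusted p with the block was between 0.46 and 0.63. In simulated tables that setting with the block found a list shifted by 0.3 log2 units in 0 of 20 tables. Its values with the block therefore cannot decide about shifts of that size or smaller, here or in the lists above. Among the 16 lists the largest shift was in metallothioneins, small proteins that bind zinc and copper. Of the 7 genes of that list, 6 were higher on average, with a median log2 fold change of 0.67 (adjusted p = 0.072 without and 0.0024 with the block). Without the inhibitor library of donor 3 this median was -0.06 (adjusted p = 0.96), and it reached 1 without the vehicle library of that donor. Leaving out both libraries of a donor gave 0.46 to 0.59 (adjusted p of at most 0.032 with the block). MT2A was at 334 ± 305 and 525 ± 463 TPM and higher in every donor (1.59-fold, adjusted p = 0.38 over all genes with the block), and it passed adjusted over the list alone with the block. MT1E (2.01-fold), MT1F (1.59-fold) and MT1G (1.59-fold) did not. All 23 G2/M genes were lower on average, by a median of -0.07 (adjusted p = 0.60 without and 0.00036 with the block), and 8 were lower in all 3 donors. The correlation estimated between these genes was 0.98, and 0.18 with the block, above the preset 0.01. The 23 genes are therefore not independent observations. BUB1B (0.869-fold), ASPM (0.871-fold), NUSAP1 (0.871-fold) and TOP2A (0.896-fold) are examples that did not pass singly. G1/S genes had a median of -0.05 (adjusted p = 0.89 without and 0.045 with the block), with CCNE2 at 0.82-fold, CCNE1 at 0.906-fold, PCNA at 0.914-fold and E2F1 at 0.931-fold. The FOXO and KLF2 quiescence genes, which mark resting T cells, had a median of 0.07 with 16 of 18 higher on average (adjusted p = 0.17 without and 0.00053 with the block). Among them were IL7R (1.22-fold), CCR7 (1.17-fold), PIK3IP1 (1.15-fold) and KLF7 (1.13-fold), which did not pass.

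**Figure D3:**
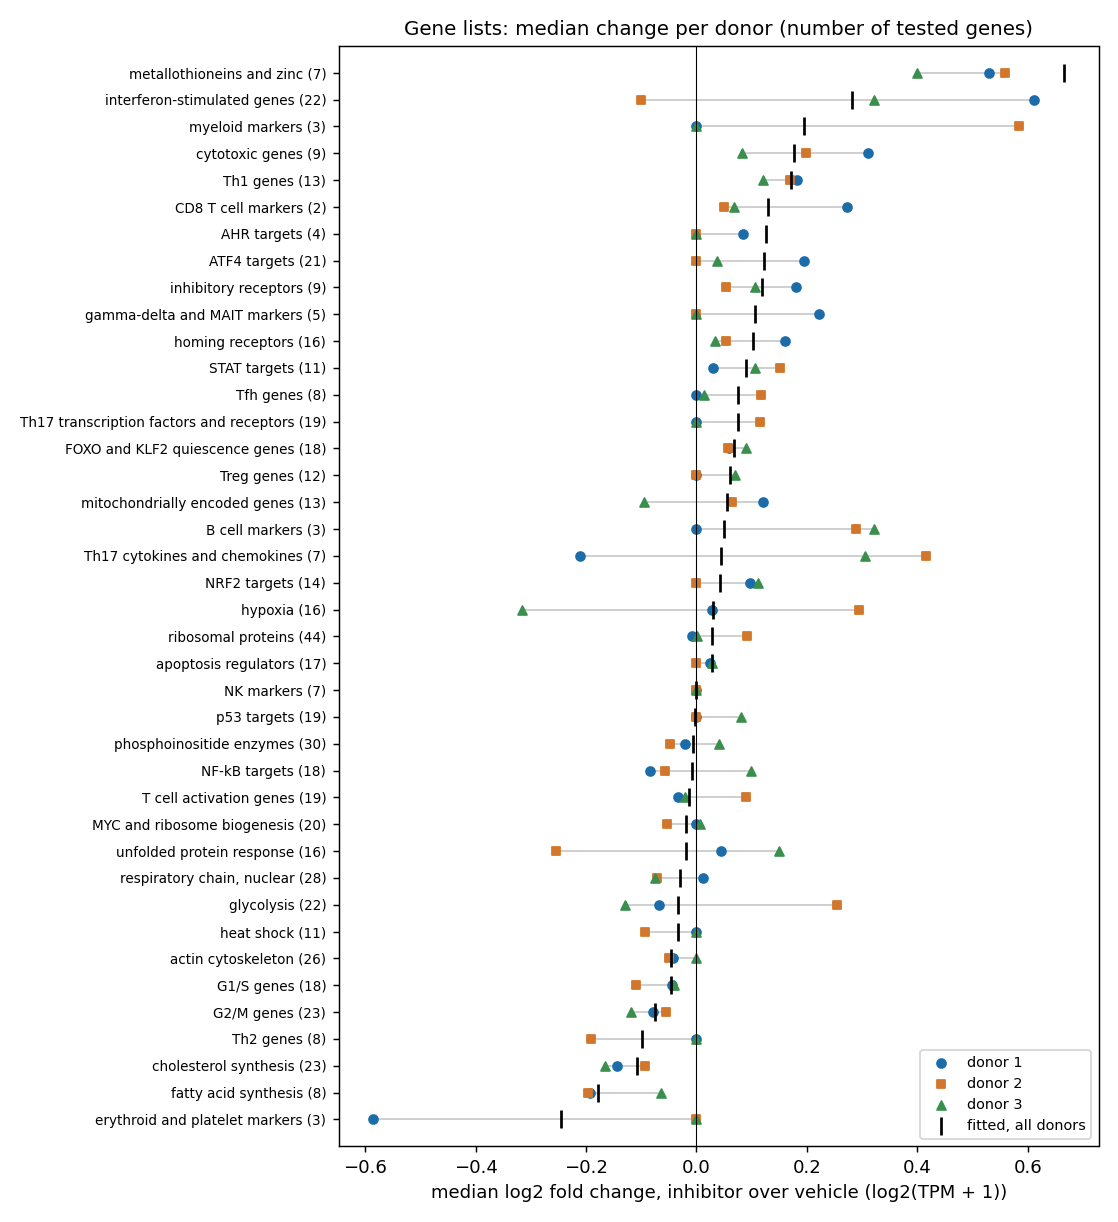
Median log2 fold change, inhibitor over vehicle, of each of the 40 gene lists, with the number of tested genes in brackets. Coloured points are the medians within each donor and the black bar is the median of the fitted values. The medians run from -0.25 (erythroid and platelet markers, 3 genes) to 0.28 (interferon-stimulated genes) and 0.67 (metallothioneins), and the donors spread on both sides of 0 in the hypoxia and glycolysis lists.

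The other lists that passed only with the block were higher by small amounts. These were inhibitory receptors (median log2 fold change 0.12, adjusted p = 0.0095 with the block), homing receptors (0.10, 0.018), STAT targets (0.09, 0.033), ATF4 targets (0.12, 0.031), NRF2 targets (0.04, 0.038) and ribosomal proteins (0.03, 0.0015), with adjusted p between 0.17 and 0.38 without the block. CTLA4, an inhibitory receptor, was at 39 ± 11.4 and 49.7 ± 12.5 TPM and ENTPD1 (CD39) at 1.21-fold. The chemokine receptors CCR8 and CCR4 stood at 0.819-fold and 1.19-fold, and the selectin ligand SELPLG at 1.16-fold. Among STAT targets were BCL6 (1.24-fold), FURIN (1.2-fold) and SOCS1 (1.15-fold), and among ATF4 targets VLDLR (1.28-fold) and DDIT4 (1.22-fold). Among NRF2 targets were SRXN1 (1.32-fold) and FTL, the ferritin light chain (1.16-fold), which passed adjusted over the list alone with the block. Ribosomal proteins were led by RPS28 at 1.10-fold, and their medians per donor were -0.01, 0.09 and 0.00. With the block, the estimated correlation was 0.48 for ribosomal proteins, 0.27 for NRF2 targets and 0.23 for ATF4 targets. These lie above the preset 0.01, so the genes of these lists are not independent observations. For inhibitory receptors, homing receptors and STAT targets it lay between -0.04 and 0.01. After quantile normalization with the block, the Th17 transcription factor, ribosomal protein, NRF2 and G1/S lists no longer passed (adjusted p of 0.078, 0.33, 0.14 and 0.069). With median-of-ratios scaling and the block, the Th17 transcription factor, NRF2 and G1/S lists no longer passed (0.053, 0.066 and 0.053).

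The remaining 23 tested lists passed in neither fit, with medians from -0.25 to 0.19 and adjusted p of at least 0.17 without and 0.064 with the block. T cell activation genes had a median of -0.01, NF-kB targets -0.01, Treg genes 0.06, Th2 genes -0.10 and Tfh genes 0.08. Glycolysis (-0.03), hypoxia (0.03), the nuclear genes of the respiratory chain (-0.03), mitochondrially encoded genes (0.05), the unfolded protein response (-0.02), heat shock genes (-0.03), p53 targets (0.00), apoptosis regulators (0.03), MYC targets and ribosome biogenesis (-0.02) and the actin cytoskeleton (-0.05) did not pass either. AHR targets had a median of 0.13 over 4 genes. Of the markers of other cells, 3 tested B cell genes had a median of 0.05, 3 myeloid genes 0.19, 5 genes of gamma-delta and MAIT cells 0.11 and 3 erythroid and platelet genes -0.25. The myeloid genes CD68 and LYZ were each at 1.67 TPM with vehicle, and at 2.67 and 2 TPM with the inhibitor.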

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

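A mean of at least 10 TPM and the block with an estimated correlation or fry were chosen after seeing the data. The count of genes higher with the inhibitor was 0 in the main analysis, 1 with a pseudocount of 0.1, 5 with 0.5, 18 with no filter on low values and 746 with sample quality weights. With the replicate block they numbered 6, with the block and a pseudocount of 0.1 they numbered 4, and with the block and no filter 26. The count of genes lower with the inhibitor was 0, against 17 with no filter, 1067 with quality weights and 23 with the block and no filter. Other settings with all libraries gave 0 in both directions. The quality weights were 12 and 12.6 for the libraries of donor 1 and at most 0.325 for the others, so these calls rest on 1 donor, and 385 of the 1813 genes had the same sign in all 3 donors. Unadjusted p under 0.05 numbered 4116 there. Leaving out libraries or donors gave 0 to 39 genes higher and 0 to 29 lower.

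Lists shifted numbered 3, against 1 with no filter, 12 at a mean of at least 5 TPM and 11 at 10, 5 with median-of-ratios scaling and 6 with quality weights. With the replicate block they numbered 16, also 16 with a pseudocount of 0.1, 17 with no filter, 13 with median-of-ratios scaling, 12 with quantile normalization and 14 at a mean of at least 10 TPM. An estimated correlation gave 0 and fry 0, with or without the block. Leaving out libraries gave 0 to 14 lists. The interferon-stimulated list passed in all 9 settings without the block that kept the libraries and camera's preset correlation. When single libraries or donors were left out, the medians of 34 of the 39 lists took both signs. They ran for interferon-stimulated genes from -0.0486 (without the inhibitor library of donor 1) to 0.78, G2/M from -0.49 to 0.34, G1/S from -0.47 to 0.34, MYC and ribosome biogenesis from -0.37 to 0.34, hypoxia from -0.29 to 0.36, the unfolded protein response from -0.21 to 0.24 and ribosomal proteins from -0.16 to 0.18. Of the other lists that passed with the block, these also took both signs: metallothioneins (-0.06 to 1), NRF2 targets (-0.25 to 0.40), cytotoxic genes (-0.20 to 0.45), FOXO and KLF2 genes (-0.17 to 0.32), ATF4 targets (-0.15 to 0.33), inhibitory receptors (-0.12 to 0.39), STAT targets (-0.05 to 0.28) and cholesterol synthesis (-0.28 to 0.02). Th17 cytokines ran from -0.31 to 0.75, Th1 genes from 0.06 to 0.18 and fatty acid synthesis from -0.26 to -0.08. Leaving out 1 library leaves a donor unpaired, so donor differences enter the comparison. For the unfolded protein response the sign also turned without both libraries of donor 2 (0.07, adjusted p = 0.042). Beyond that, the cause was not tested.

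Named genes kept their side of the threshold in 2417 of 2472 values with all libraries, and 54 came to pass, 34 of them with sample quality weights. Since no gene passed in the main fit, keeping the side means only that a gene still did not pass, which says little about stability. A change of sign within 1 SE of a gene that did not pass was counted as no change. Such changes numbered 229 among the 175 named genes, over the settings with all libraries and those with libraries left out. The donor block changed no call beyond those given. Whole-number TPM limit what can be seen in genes of a few TPM, and the sequencing depth behind each value is unknown.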

Other observations

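The lists and tests of mitochondrial genes, of the interferon-gamma response, of steps of 1 TPM, of CD8 T and NK cell markers and of the counts of genes higher and lower in other splits were chosen after seeing the data, as were the comparison of short RNAs with all genes, the use of both fits without donor 1 and the genes named only here, and the other tests were set down before their results were seen.

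Enzymes of the TCA cycle and of pyruvate dehydrogenase, which oxidise pyruvate in mitochondria, lay slightly lower with the inhibitor. Of 18 genes tested, 16 were lower on average and 11 were lower in all 3 donors, with a median log2 fold change of -0.09 and medians per donor of -0.10, -0.09 and -0.11. PDHA1 (-0.27), FH (-0.20), DLAT (-0.19) and CS (-0.15), fumarase and citrate synthase among them, had the same sign in every donor, and none passed the test over all genes in either fit. As a list they did not pass without the donor block (adjusted p = 0.084) and passed with it (1.5e-05). That call was lost with an estimated correlation (adjusted p = 0.99, and 0.45 with the block), and the genes were noticed in these data before the list was written. The 78 genes of the mitochondrial ribosome had a median of -0.04, with 55 lower on average and a median of 0 in donor 1 (adjusted p = 0.50, and 0.0043 with the block, or 0.99 and 0.60 with an estimated correlation). The lists fixed beforehand did not pass: nuclear genes of the respiratory chain had a median of -0.03 (adjusted p = 0.17, and 0.064 with the block; 0.01 in donor 1) and mitochondrially encoded genes 0.05. A lower expression of TCA cycle enzymes with the inhibitor stays open.

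The 6 genes that passed with the donor block all have a mean of at most 2.33 TPM, and identical steps in 3 donors leave almost no spread. When each value was redrawn evenly within 0.5 TPM of its whole number, 0 of the 6 were kept in the median of 100 redrawn tables, but 0 of the 6 had every pair more than 1 TPM apart, so the redrawing would lose such changes whatever caused them and decides nothing about rounding. No gene (0) passed with the block among genes of at least 10 TPM, where 774 had an unadjusted p under 0.05. The 3 other splits that part every donor pair called at most 4 genes (1 split of the 4, the real one, gave as many as 6), and 4 splits are too few for a share under 0.05. Steps of 1 TPM in low genes are thus a candidate explanation for these calls, CCL20 included, and an effect of the inhibitor on CCL20 stays open.

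The interferon-stimulated and Th1 lists were higher, which the treatment or the donors and cultures may account for. For the interferon-stimulated genes a dependence on donor 1 stays open: without its libraries the median was 0.13 with an adjusted p of 0.344, or 0.037 with the block, and the medians of donors 2 and 3 were -0.10 and 0.32. Stronger interferon-gamma signalling also stays open: 24 genes of that response had a median of 0.09 (adjusted p = 0.090, and 0.0016 with the block, or 0.99 and 0.60 with an estimated correlation), 17 were higher on average, 10 were higher and 1 lower in all 3 donors, and the donor medians were 0.12, 0 and 0.13. A larger share of CD8 T or NK cells stays open. The 5 of their markers with at least 5 TPM had a mean log2 fold change of 0.0535 ± 0.0854, against the Th1 median of 0.17. That SE is over the 5 markers and not over donors. Among them, KLRC1 (0.30) and CD8B (0.15) were higher in all 3 donors, while KLRD1 (-0.14) and NCR1 (-0.13) were lower on average. The isolation of naive CD4+ cells would remove most such cells. A treatment effect on Th1 genes, whose donor medians lay between 0.12 and 0.18, is also open.

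Of 106 genes that differed by 2-fold or more in either direction, 50 were short structured RNAs (small nuclear, small nucleolar or miscellaneous RNAs), 28 higher and 22 lower. SNORA52 was listed at 0 in the 3 vehicle libraries and at 6, 21 and 10 TPM with the inhibitor, without passing in either fit (adjusted p = 0.71, and 0.40 with the block), and RN7SK was at 1.75-fold. Of the 131 tested short RNA genes, 10 (7.63%, SE 2.32) were higher and 3 lower in all 3 donors, against 6.13% higher among all tested genes, and their median log2 fold change was 0 with a bootstrap SE of 0.109. The rule set beforehand asked for a median above 0.2 for a rise of the class, and took a median close to 0 as speaking against it. The median of 0 met the latter. The limit of 25% also set was too high because whole numbers often tie. A bound of 2 SE above the median, which was not part of that rule, reaches 0.218, so by that bound a rise by 0.2 stays open. There were 1.07 short RNA genes higher for each one lower, and a median absolute log2 fold change of 0.91 against 0.07 for protein-coding genes, which is consistent with a wide spread of short RNAs between libraries (no biological explanation was tested).

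The 6 libraries allow 10 splits of 3 against 3, too few for a share under 0.05. The real split called 0 genes as higher and 0 as lower, so all 10 splits give as many by construction and the regrouping says nothing about these counts; the highest other counts were 25 and 32. For gene lists, 9 of the 10 splits shifted as many as the real one (3), and the highest other shifted 20. The splits with 20 lists or with 25 or 32 genes part only 1 donor pair and so follow the donors, a structure of the samples. Among the splits that part all 3 pairs, the others shifted 0, 4 and 3 lists without the block. With the block they shifted 2, 8 and 8 against 16 for the real split, which was the 1 split of the 4 to give as many, and their counts of genes with an unadjusted p under 0.05 were 456, 608 and 1034 against 1214.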
